A study of Mus musculus with 2 samples.

How the data were processed

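RNA-seq libraries from the livers of CD-1 mice were compared, 1 from the Control group and 1 from the group given titanium dioxide nanoparticles (NP). Per the labels' protocols, frozen liver was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. Read length, strandedness and the number of animals behind a library were not given in the sources used here. TopHat2 2.1.0, Cufflinks 2.2.1.0 and the mouse build mm9 are named in the submitters' processing notes, and their roles and settings are not given in the sources used here. The deposited tables hold FPKM values, per the file headers in the isoform tracking format of Cufflinks, with a 95% interval, a length and a status for each row. They also hold read coverage, per the file headers, a signal that is not scaled to library size. Each table has 119289 rows, of which 87656 are transcripts and 31633 are spans of whole genes. All 31633 span rows have a length equal to the genomic span, so they can also take intronic reads.

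FPKM of all rows of a gene identifier were summed, and the half-widths of the row intervals were combined in quadrature. This leaves out the covariance between rows. The upper limit given for a row at 0, such as 0.256 FPKM for a Ddit3 transcript in Control, was not used. A gene listed at 0 thus has an interval of no width here, and counts of separate intervals treat a 0 as exact. Gene names and coordinates were those of the files, and a genome annotation of build mm9 was not used here. Start positions were converted to count from 1. Genes were kept with a mean of at least 1 FPKM over both libraries, an OK status in all rows, a transcript of at least 300 nt and no name of a microRNA, small nuclear or nucleolar RNA. Of 37146 genes, 10533 remained; Apob was left out because 5 of its rows had failed status. Ratios were log2((NP + 1)/(Control + 1)), a scale that understates differences of low genes. Ratios and folds given for single genes are those of the FPKM values themselves, while counts past 1.5-fold or 2-fold use the log2(FPKM + 1) scale unless plain FPKM is named.

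With 1 library per group no test, standard error or p-value was possible, and a fixed size rule of 2-fold was used. For each of 41 gene lists the median ratio was ranked among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list needed 5 members past the filter, and members were counted at 1.5-fold on the log2(FPKM + 1) scale. Genes to be named were 19 fixed genes, the 10 highest and 10 lowest ratios among genes with a mean of at least 5 FPKM, and up to 4 members at each end of each list. The result of 1 of the fixed genes is not reported here. The lists, this rule, the filter, the thresholds and the alternatives listed first below were fixed before the data were examined. Because the 20 most extreme genes were all listed at 0 in 1 library, the 10 highest and 10 lowest above 0 in both were added after the values were seen.

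The depth of a library was not given as a number of fragments. Coverage per FPKM, 2.29 in Control and 2.92 in NP, gave the relative depth. The size rule and the percentile were tested on simulated data made from the mean values of the 10533 genes, with a noise of 0.25 in log2. The rule caught 4.48% of genes simulated at 1.5-fold, 53.7% at 2-fold and 100% at 4-fold, and 0% of unchanged genes. The noise was the same for all genes, and changes were placed only in genes with a mean of at least 5 FPKM. Genes listed at 0 in 1 library were not simulated. The 0% therefore follows from this setting and gives no error rate for the real counts. Of 1000 simulated lists without a shift, 5.8% fell outside the middle 95%, and 90.8% of 1000 lists of 25 genes shifted by 0.2 lay above it. The number of lists was raised to 1000 after the first 100 put 13 outside. The other 900 put 45 outside, and why the first 100 held more was not examined. All these list rates hold for members with independent noise of equal size. They give no error rate for the real lists, whose members are regulated together. Alternatives covered the pseudocount, the filter, 3 scalings of the NP library, the row used for a gene, the status, the size rule and the number of bins. Added after the data were examined were versions without genes at 0, without gene-span rows, without overlapping genes and without multi-copy gene families. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.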

Results

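The series compared the liver transcriptome of CD-1 mice given titanium dioxide nanoparticles by mouth with that of mice given phosphate-buffered saline. CD-1 is an outbred laboratory strain. The nanoparticle (NP) group received 50 mg per kg body weight per day of a suspension dispersed with ultrasound for 30 min. Each group was represented by 1 RNA-seq library, called Control and NP here, and how many mice entered a library was not stated in the labels. Values were FPKM (fragments scaled to row length and to all mapped fragments) with the 95% interval that Cufflinks gives for a single library. That interval covers the uncertainty of the estimate within a library and holds no spread between animals. With 1 library per group no difference had a replicate check, so all statements below describe these 2 libraries and not the treatment. The total number of mapped fragments was not given in the sources used here. Read coverage per unit of FPKM was 2.29 in Control and 2.92 in NP, a ratio of 1.28, so NP was the more deeply covered library. The median upper half-width of the interval was 25.9% of the value in Control and 24.2% in NP for genes at 1 to 5 FPKM. It was 6.62% and 6.33% for genes above 50 FPKM.

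The first question was how far the libraries differed across all genes. Of 10533 genes with a mean of at least 1 FPKM, 120 were at least 2-fold higher and 198 at least 2-fold lower in NP, on the scale of log2(FPKM + 1). Values lay within 1.5-fold for 91.1% of genes, and the median log2 ratio was -0.03. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.97. Among genes with a mean of at least 5 FPKM, the 10 highest and the 10 lowest ratios all belonged to genes listed at 0 in 1 library. These included Dctn3, a dynactin subunit listed at 0 in Control and at 75.3 FPKM in NP, and Nme3, a nucleoside diphosphate kinase at 47.2 FPKM in Control and listed at 0 in NP. Such a 0 can be a failed estimate, so no fold is given for these genes. Without genes at 0, 76 genes were 2-fold higher and 145 lower. Of those 145, 79 were ribosomal protein genes, Mup genes, Gm-numbered genes or pseudogenes, against 8 of the 76. With both kinds of gene left out, 68 were higher and 66 lower, so that the share of higher genes went from 37.7% to 50.7%. Leaving out only genes at 0 lowered the share to 34.4%, and leaving out only the families raised it to 51.9%. Both versions were chosen after the values were seen. Among genes above 0 in both libraries with a mean of at least 5 FPKM, a set chosen after the values were seen, Cyp2b9, Gm20481, Hspa1b, Saa1, Ces2a and 1100001G20Rik had the highest ratios on the log2(FPKM + 1) scale. All FPKM of Gm20481 lay in its gene-span row, and without such rows it was at 0 in both libraries. BC021614, Mettl5, Mup16, Mup18 and 2310001H17Rik had the lowest on that scale. The NP value of Mettl5, 0.863 FPKM, lay wholly in its gene-span row.

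**Figure D1:**
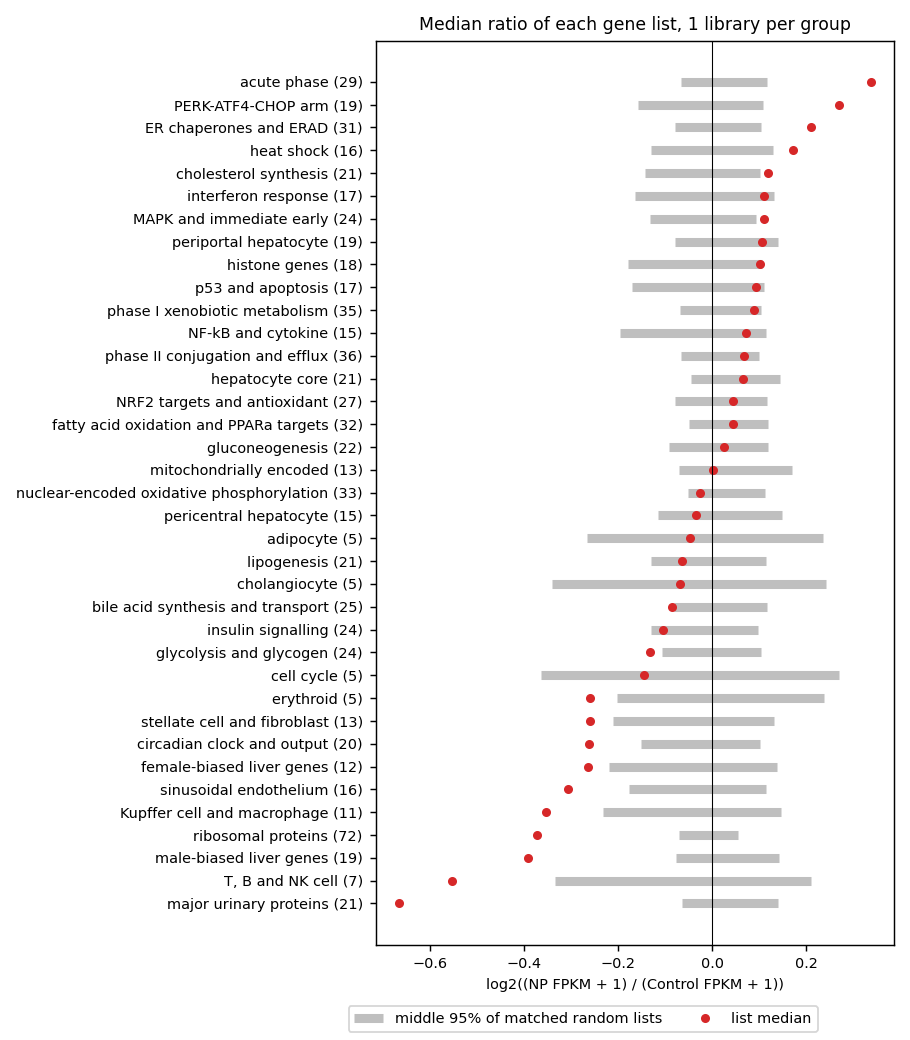
Median log2((NP FPKM + 1)/(Control FPKM + 1)) of the members of each gene list (red points, members past the filter in brackets) with the middle 95% of 10000 random lists matched on expression (grey bars), from 1 library per group. The acute phase list has the highest median, 0.34, and the major urinary protein list the lowest drawn, -0.67; the exocrine pancreas list, at -1.74, is not drawn.

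The series title names endoplasmic reticulum (ER) stress, and genes of ER protein folding and ER-associated degradation were higher in NP as a group. Herpud1, which acts in ER-associated degradation, was at 199.9 FPKM (interval 189 to 211) in Control and 502 (481 to 523) in NP, a ratio of 2.51. Dnajb9, an ER co-chaperone, was at 36.5 and 89.6 FPKM. Hspa5, the main ER chaperone (BiP), was at 467 (446 to 488) and 721 (689 to 752) FPKM, a ratio of 1.54. Syvn1, an ER ubiquitin ligase, was at 42.0 and 96.9 FPKM, and Manf, a secreted ER protein, at 244 and 473 FPKM. The sensors Atf6 (7.73 and 7.15 FPKM) and Ern1 (13.3 and 12.5 FPKM) had overlapping intervals, as had Xbp1, the transcription factor spliced by the Ern1 product, at 80.8 and 90.7 FPKM. Members of all lists were counted on the log2(FPKM + 1) scale, which shrinks the ratios of low genes. Of 31 list members, 9 were at least 1.5-fold higher, 0 at least 1.5-fold lower and 22 between, and 16 had an NP interval wholly above that of Control. Intervals of abundant genes are narrow, so a small ratio can separate them. Coordinates are those of the mm9 build in the files. Herpud1 spans chromosome 8 from 96910338 to 96919277, Dnajb9 chromosome 12 from 45306884 to 45311055 and Hspa5 chromosome 2 from 34627490 to 34632051. The list median was 0.21, above all 10000 matched random lists (percentile 100), whose middle 95% ran from -0.08 to 0.10. Syvn1 overlaps Mrpl49 and Manf overlaps Vprbp, both listed at 0 in NP; without overlapping genes, a set chosen after the values were seen, the median of 28 members was 0.18 (percentile 99.98).

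**Figure D2:**
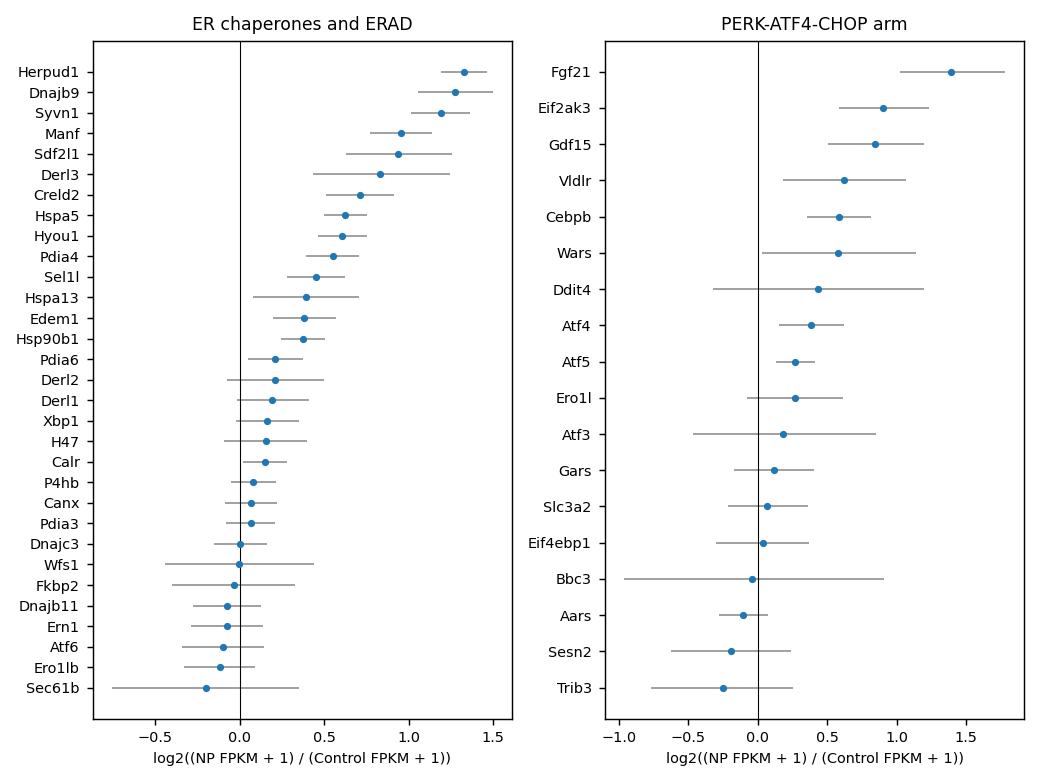
Log2((NP FPKM + 1)/(Control FPKM + 1)) of each member of the ER chaperone and PERK-ATF4-CHOP lists that passed the filter of a mean of at least 1 FPKM and was above 0 in both libraries, with a bar from the lowest to the highest ratio that the 95% intervals of the 2 libraries allow. Herpud1 and Fgf21 stand highest, at 1.32 and 1.39, and Sec61b and Trib3 lowest, at -0.20 and -0.25; Ddit3, listed at 0 in Control, is not drawn.

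Genes of the PERK-ATF4-CHOP arm of the ER stress response were also higher as a group, with members that did not share the direction. Fgf21, a hormone secreted by the liver, was at 21.5 FPKM (17.9 to 25.2) in Control and 58.2 (52.3 to 64.1) in NP. Eif2ak3, which encodes PERK itself, was at 8.73 FPKM in NP, 2.08 times its Control value, and Gdf15, a stress-induced cytokine, at 17.5 and 32.2 FPKM. Atf4, the transcription factor of this arm, was at 58.4 (53.2 to 63.5) and 76.4 (70.6 to 82.2) FPKM. Trib3 and Sesn2, both known ATF4 targets, had overlapping intervals, at 7.51 and 6.16 FPKM and at 3.64 and 3.05 FPKM. Ddit3, which encodes CHOP, was listed at 0 in Control and at 23.8 FPKM in NP. Its span on chromosome 10, from 126727830 to 126733344, overlaps Mars, the methionyl-tRNA synthetase gene, which was lower in NP by -0.42 in log2 of FPKM times length. Of 19 members, 5 were at least 1.5-fold higher, 0 lower and 14 between. The median was 0.27 (percentile 100), and 0.27 (percentile 99.98) without genes at 0. That version drops only Ddit3, and a median can move little when 1 extreme member is left out. The mean of 0.56 includes the large ratio of Ddit3.

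The title also names plasma glucose, and the genes of glucose production differed little. Pck1, which commits carbon to gluconeogenesis (chromosome 2, 172978549 to 172984774), was at 1406 FPKM (1350 to 1463) in Control and 1376 (1317 to 1434) in NP. G6pc, which releases free glucose, was at 247 (236 to 258) and 283 (271 to 295) FPKM, a ratio of 1.15. Of 22 gluconeogenesis genes, 0 were 1.5-fold higher or lower, and the median was 0.03 (percentile 58.9). The NP interval lay wholly above that of Control for 7 of these genes and wholly below for 2. In the glycolysis and glycogen list, Gys2, the liver glycogen synthase, was at 68.6 and 44.6 FPKM, and Ppp1r3b, which targets a phosphatase to glycogen, at 24.1 and 47.3 FPKM. Of the 24 members of this list, 1 was 1.5-fold higher and 1 lower, yet the median of -0.13 lay low (percentile 0.84), since 18 members were below 0. Of 24 insulin signalling genes, 0 were 1.5-fold higher or lower on the log2(FPKM + 1) scale, and 1 was lower by plain FPKM, with a median of -0.10 (percentile 6.64). That gene was Irs1, an insulin receptor substrate, which was at 3.20 and 1.85 FPKM and overlaps another expressed gene, and Igfbp1, an insulin-repressed gene, was at 62.1 and 80.4 FPKM.

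Acute phase genes, which the liver secretes in inflammation, had the highest median of all lists. Saa1, a serum amyloid A gene on chromosome 7 from 53995871 to 53998350, was at 24.9 FPKM (19.9 to 29.9) in Control and 143 (130 to 156) in NP. Its near-identical neighbour Saa2 was at 8.17 and 35.3 FPKM, and because reads of the pair can be exchanged their sum is the safer value, 33.1 and 178 FPKM. Apcs, which encodes serum amyloid P, was at 59.8 and 171 FPKM. Of 29 members, 11 were 1.5-fold higher and 0 lower, with a median of 0.34 (percentile 100). Ratios of 6 members were below 0, and the NP interval lay wholly below that of Control for 2, Serpina3k at 3253 and 2650 FPKM and Serpina3m at 336 and 264 FPKM. Saa3, a 3rd serum amyloid A gene, was at 10.8 and 8.06 FPKM with overlapping intervals. The NF-kB and cytokine list had 1 of 15 members 1.5-fold higher and 1 lower, with a median of 0.07 (percentile 92.2). The interferon list had 1 of 17 higher and 0 lower (median 0.11, percentile 95.5).

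In the heat shock list, Hspa1b, an inducible cytosolic HSP70 gene, was at 8.07 FPKM (6.64 to 9.49) in Control and 60.1 (56.1 to 64.1) in NP. Bag3 and Dnajb1, which encode co-chaperones of HSP70, were at 7.65 and 19.9 FPKM and at 11.0 and 22.7 FPKM. The other 13 of 16 members were within 1.5-fold, among them Hspb1 at 44.3 and 29.7 FPKM. The median was 0.17 (percentile 99.5, bootstrap range -0.10 to 0.35), which moved inside the middle 95% without overlapping genes (percentile 96.4). Of 24 MAPK and immediate early genes, 4 were 1.5-fold higher and 3 lower (median 0.11, percentile 98.8, bootstrap range -0.13 to 0.28). Fos was at 2.48 and 5.74 FPKM and Gadd45g at 11.6 and 25.5 FPKM, while Gadd45a, at 9.95 FPKM in Control, was 3.32-fold lower and Myc was at 4.82 and 2.17 FPKM. The p53 and apoptosis list had 1 of 17 higher and 0 lower (median 0.09), and all 5 measured cell cycle genes were within 1.5-fold on the log2(FPKM + 1) scale, with 1 higher and 1 lower by plain FPKM.

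Xenobiotic and antioxidant genes differed gene by gene. Cyp2b9 was at 0.369 FPKM (0.0192 to 0.719) in Control and 12.0 (10.4 to 13.7) in NP, and Ces2a, a carboxylesterase, at 25.1 and 129 FPKM. Cyp3a11, the main CYP3A of mouse liver and a target of the pregnane X receptor, was at 2496 and 3664 FPKM. Cyp1a1, a target of the aryl hydrocarbon receptor, was near the floor at 0.484 and 0.205 FPKM, and Cyp2b10 was at 0.595 FPKM in Control and listed at 0 in NP. Of 35 phase I genes, 7 were 1.5-fold higher and 2 lower (median 0.09, percentile 94.3), and of 36 phase II and efflux genes 3 were higher and 1 lower (median 0.07, percentile 90.1). Of 27 NRF2 and antioxidant genes, 2 were 1.5-fold higher and 0 lower on the log2(FPKM + 1) scale (median 0.04, percentile 73.3). Those 2 were the metallothioneins Mt1, at 74.6 and 175 FPKM, and Mt2, at 30.0 and 50.8 FPKM. By plain FPKM the low NRF2 target Nqo1 was the 3rd, at 1.72 and 2.77 FPKM, and Hmox1 was at 8.41 and 9.59 FPKM, both with overlapping intervals.

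Single genes of bile acid synthesis and of lipogenesis differed by over 2-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6192759 to 6202780), was at 35.5 FPKM (33.1 to 37.9) in Control and 13.7 (12.4 to 14.9) in NP, 2.60-fold lower. Cyp7b1, of the alternative pathway, was at 236 and 82.8 FPKM. Of 25 bile acid genes, 2 were 1.5-fold higher and 4 lower, and the median of -0.09 (percentile 2.07) moved inside the middle 95% with 5 expression bins (percentile 4.79) or without overlapping genes (percentile 4.78). All 21 cholesterol synthesis genes lay within 1.5-fold, with a median of 0.12 (percentile 98.5) that also moved inside without overlapping genes (percentile 95.8). In the lipogenesis list 1 of 21 was higher and 2 lower (median -0.07, percentile 18.9). Srebf1, a regulator of lipogenesis whose span overlaps another expressed gene, was at 14.0 and 5.33 FPKM, and Fasn, the fatty acid synthase, at 7.04 and 6.54 FPKM. Of 32 fatty acid oxidation and PPARa target genes, 4 were higher and 0 lower (median 0.04, percentile 61.7). Among these 4 were Cyp4a14, at 1209 and 2244 FPKM, and Pdk4, at 7.92 and 13.7 FPKM.

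Genes with a higher level in male than in female liver were lower in NP as a group. Elovl3, a fatty acid elongase on chromosome 19 from 46206387 to 46210184, was at 174 FPKM (165 to 184) in Control and 43.6 (40.1 to 47.2) in NP. Hsd3b5, a steroid dehydrogenase, was at 42.7 and 16.3 FPKM, and Nudt7, a peroxisomal hydrolase, at 156 and 65.9 FPKM. Of 19 male-biased genes, 8 were 1.5-fold lower and 0 higher, with a median of -0.39 (percentile 0, below all random lists). Ratios of 4 members were above 0, and the NP interval lay wholly above that of Control for 1, Cyp4a12a at 166 and 186 FPKM. That list shares Cyp7b1 and Slco1a1 with the bile acid list and 4 genes with the major urinary protein (Mup) family. All 21 Mup genes were lower and 13 by at least 1.5-fold, but they are near-identical and single members are uncertain. Their sum was 1.48-fold lower in NP. Of 12 female-biased genes 2 were 1.5-fold higher, Cyp2b9 and Acot3, and 1 was lower, Cyp3a44. By plain FPKM 3 were lower, with Cyp3a41a and Cyp17a1 added. Their median was -0.26 (percentile 0.77, bootstrap range -0.37 to 0.14) and their mean 0.11, opposite in sign, and the median was 0.14 among genes with a mean of at least 5 FPKM. The Y-linked Ddx3y was at 14.3 and 16.0 FPKM, and Xist, expressed from the inactive X chromosome, was at 0.0184 FPKM in Control and listed at 0 in NP.

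Clock and clock output genes were lower in NP more often than higher. Tef, a clock output transcription factor, was at 36.6 FPKM (34.0 to 39.1) in Control and 22.1 (20.3 to 23.9) in NP, and Nr1d2, a repressor within the clock, at 23.6 and 14.3 FPKM. Arntl, which encodes the activator BMAL1, was at 3.81 and 7.21 FPKM, and Per1 at 8.36 and 9.15 FPKM. Dbp, another output gene, was at 31.7 FPKM in Control and listed at 0 in NP. Its span overlaps Sphk2, whose higher value in NP made up 0.228 of the missing FPKM times length. That missing amount includes the gene-span row of Dbp, at 6.48 FPKM in Control, which can also take intronic reads. Of 20 members 8 were 1.5-fold lower and 2 higher, with a median of -0.26 (percentile 0.03). The labels did not state the time of day at which livers were taken.

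Median ratios of the endothelial, Kupffer, stellate, lymphoid and erythroid marker lists were lower in NP, while those of cholangiocytes and adipocytes lay within the range of random lists. All 16 sinusoidal endothelial genes had a ratio below 0, with a median of -0.31 (percentile 0.04), and Clec4g was at 44.6 and 30.6 FPKM. Kupffer cell and macrophage genes had a median of -0.35 over 11 members (percentile 0.27), with Clec4f, a Kupffer cell lectin, at 18.4 (14.6 to 22.3) and 7.63 (5.28 to 9.99) FPKM. The bootstrap range of the median was -0.53 to 0.03, and Folr2 (0.974 and 1.67 FPKM), Lyz2 (8.89 and 9.98) and Slc40a1 (44.8 and 45.7) had ratios above 0 with overlapping intervals. The stellate cell list had a median of -0.26 over 13 members. The T, B and NK cell list had -0.55 over 7 members, led by the MHC class II genes H2-Aa, H2-Ab1 and Cd74, of which Cd74 was at 17.8 and 10.2 FPKM. These 3 and H2-Eb1 (1.54 and 0.736 FPKM) act in antigen presentation and are not specific to lymphocytes. The B cell gene Ighm (4.08 and 2.46 FPKM) had overlapping intervals. The T cell gene Cd3g (0.810 and 1.21 FPKM) and the plasma cell gene Igj (1.26 and 2.33 FPKM) had ratios above 0 with overlapping intervals. A bootstrap of the members put the median of this list between -0.94 and 0.28, so no lower level of lymphocyte genes is read from it. On the log2(FPKM + 1) scale 1 of 11 Kupffer cell genes and 0 endothelial or stellate genes were at least 1.5-fold lower. In the T, B and NK cell list 3 of 7 were, namely H2-Aa, H2-Ab1 and Cd74. By plain FPKM, 4 Kupffer cell genes, 5 genes of the T, B and NK cell list, 5 endothelial and 2 stellate genes were. The erythroid list had -0.26 over 5 members, of which 0 were 1.5-fold lower on either scale, with Alas2 at 38.3 and 45.6 FPKM and a bootstrap range of -0.45 to 0.25. Cholangiocyte genes had a median of -0.07 (percentile 43.4) and adipocyte genes -0.05 (percentile 39.4), each over 5 members, while the neutrophil list had 3 measured genes, too few for a percentile. Of these Lcn2, also an acute phase gene, was at 1.31 and 4.23 FPKM, and S100a8 and S100a9 had overlapping intervals. Hepatocyte core genes had a median of 0.07 over 21 members (percentile 59.2), within which Alb, serum albumin, was at 21660 and 30741 FPKM. Pericentral genes had a median of -0.03 over 15 members (percentile 21.5) and periportal genes 0.11 over 19. These shifts accompanied the higher acute phase and ER chaperone medians in the same library.

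Ribosomal protein genes were lower in NP, with a median of -0.37 over 72 genes (percentile 0). Of these, 26 were at least 1.5-fold lower and 0 higher, but many have processed pseudogenes that can take their reads. Rps20, at 49.9 and 13.1 FPKM over all rows of the gene, had a ratio of -1.86 on the log2(FPKM + 1) scale. In its highest row alone that ratio was 0.24. Rpl35a was at 27.3 FPKM in Control and listed at 0 in NP. The abundant Rpl13a, among the members with the highest ratios, was at 593 and 705 FPKM, and the FPKM sums of the whole family differed by a ratio of 0.968. Nuclear-encoded oxidative phosphorylation genes had a median of -0.03 (percentile 9.95). The 13 mitochondrially encoded genes past the filter, 11 protein-coding and 2 ribosomal RNA genes, had a median of 0.00 (percentile 20.2). All mitochondrially encoded rows together took 12.5% of the FPKM sum in Control and 10.2% in NP. Most of that difference lay in mt-Atp8, too short for the filter, which was at 14644 FPKM in Control and listed at 0 in NP.

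**Figure D3:**
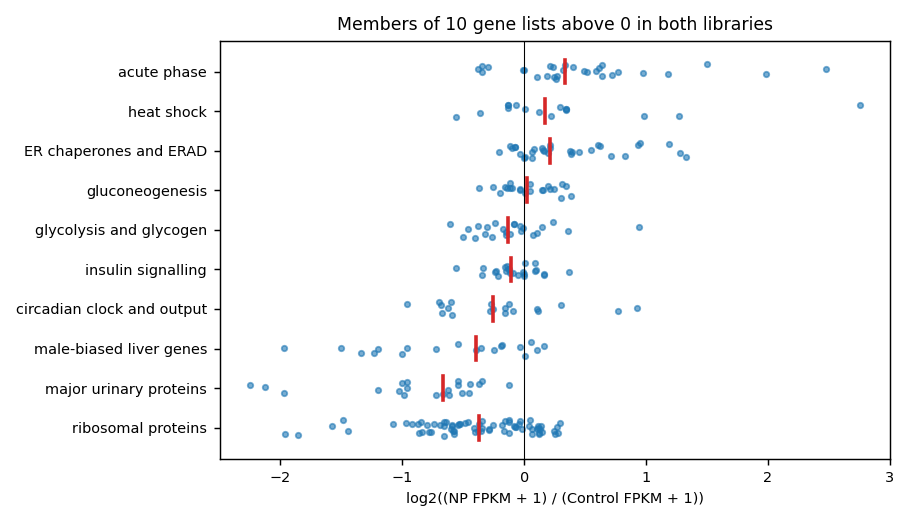
Log2((NP FPKM + 1)/(Control FPKM + 1)) of the members of 10 gene lists that were above 0 in both libraries (blue points, scattered vertically for legibility) with the median of those members (red bars). Acute phase, heat shock and ER chaperone members extend to the right, gluconeogenesis members lie near 0, and male-biased, Mup and ribosomal protein members extend to the left.

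Of the 38 lists with at least 5 measured members, 6 lay above and 13 below the middle 95% of random lists, where 1.9 would fall outside by chance if lists held unrelated genes. Members of a list are regulated together, so list percentiles rank these libraries' values and are no test of the treatment.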

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

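Versions without genes at 0, overlapping genes, gene-span rows or gene families were chosen after the values were seen; the others were planned. The 5 lists named by the title (ER chaperones, PERK-ATF4-CHOP, gluconeogenesis, glycolysis and glycogen, insulin signalling) had medians within their bootstrap ranges in all 60 recomputed values. These ranges are wide, as for ER chaperones at 0.08 to 0.45. Some settings, such as the status and the 3 scalings, could hardly move a median. Against 120 genes higher and 198 lower by 2-fold, a pseudocount of 0.1 gave 191 and 337 and a pseudocount of 5 gave 56 and 65. A mean of at least 5 FPKM gave 65 and 84. The row with the highest mean FPKM gave 202 higher genes. A 1.5-fold rule gave 379 and 561 and a 4-fold rule 47 and 50, as their construction implies. Without genes at 0, 76 were higher, and without overlapping genes 71. Without ribosomal protein, Mup, Gm-numbered and pseudogene names 101 were lower, and without these and genes at 0 the counts were 68 and 66. The other 18 counts stayed within 1.5 times. The 3 scalings shifted all ratios by 0.01, -0.01 and 0.03 in log2. Of named-gene values, 105 left the range of their intervals and 2155 did not; the 105 were mostly from a pseudocount of 5 (36) or 0.1 (32) or the highest row (32). Of the other lists' medians, 4 moved out of their bootstrap range, 1 with a pseudocount of 0.1, 2 with a pseudocount of 5 and 1 with the highest row. In all, 2 values reversed: the female-biased list had a median of 0.14 at a mean of at least 5 FPKM, where fewer genes were left, and Rps20 had 0.24 in its highest row; the cause was not tested. No replicate could be left out, and no paired analysis was possible because each group held 1 library. Depth limited genes near 1 to 5 FPKM, whose interval half-widths were about 25.9% and 24.2%.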

Other observations

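All tests of explanations in this part were chosen after the values they concern were seen. Digestive enzyme genes of the exocrine pancreas, a list fixed beforehand, were present at low level in Control and mostly listed at 0 in NP. Of 20 listed genes, 19 were above 0 in Control and 5 in NP. Ctrb1, a chymotrypsinogen gene, was at 4.92 and 0.130 FPKM, Clps, colipase, at 2.92 FPKM in Control and listed at 0 in NP, and Pnlip, pancreatic lipase, at 2.35 FPKM and listed at 0. Cela1 was at 12.6 and 8.95 FPKM, and the list without it summed to 23.7 FPKM in Control and 0.489 in NP. Beside the higher Hspa1b, the neighbouring Gm20481 on chromosome 17 (35106857 to 35109081) was at 5.91 and 54.3 FPKM. All of it lay in the gene-span row. Hspa1a, chosen after its values were seen, was at 0.593 FPKM in Control and listed at 0 in NP. Together, Hspa1a and Hspa1b summed to 8.66 FPKM in Control and 60.1 in NP. Whether fragments of Hspa1a were assigned to Gm20481 or to Hspa1b was not tested, so the 0 of Hspa1a is not read as absence.

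Genes listed at 0 in 1 library and at 5 FPKM or more in the other numbered 57. Of these 82.5% (Wilson 95% interval 70.6 to 90.2) overlapped another expressed gene, against 11.6% (10.9 to 12.3) of 8667 other genes. In 32 of the 47 with a partner, the partner was higher in the library with the 0 by at least 50% of the missing FPKM times length. This count had no upper limit and no comparison with overlapping genes that were not at 0. Some gains exceeded the missing amount, as for Syvn1 beside Mrpl49 (5.30 times) and Manf beside Vprbp (4.89 times). Missing fragments alone cannot give such gains. The overlap share goes with fragments of overlapping genes being assigned to 1 gene, but the partner count cannot decide it. In 8 others the partner was higher by less, in 7 it was lower in the library with the 0, which goes against such assignment there, and 10 of the 57 had no partner. For Ddit3, the joint total with Mars differed by 0.20 in log2, against 0.48 if the NP level of Ddit3 came on top of an unaltered Mars. Without gene-span rows the joint total differed by -0.06. The 0.48 includes the gene-span row of Ddit3, at 3.05 FPKM in NP, so it is no yardstick for the -0.06. The joint totals may mean that Ddit3 fragments went to Mars in Control, but the bound used was set after a look at the values. A difference in Ddit3 between the libraries stays open.

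Male-biased genes were lower in NP as a group. Female RNA in that library is argued against by the 4 Y-linked genes, whose median was 0.20, and by Xist listed at 0. Exchange of reads among Mup genes is argued against as the whole source, since the 15 members outside that family had a median of -0.24, below the middle 95% of random lists (-0.10 to 0.15). A different time of day at collection cannot be told apart from the treatment, because clock genes without those at 0 also differed, with a median of -0.25 (random lists -0.15 to 0.11), and the labels give no time. A response to the nanoparticles stays open and untested, as does a difference between individual mice.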
